A study of Homo sapiens with 4 samples.

How the data were processed

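Gene expression was measured in A549 cells, an established epithelial line from a human lung adenocarcinoma, on 4 one-colour Agilent arrays. Per the labels' protocols, cells in 6-well plates were given recombinant extracellular GPBP-1 (Goodpasture antigen-binding protein, isoform 1) at 200 ng/mL or its buffer TBS for 3 h. RNA from the lysed cells was labelled with Cy3 by a low-input amplification kit. Arrays 1 and 2 of each group take their numbers from the labels. The labels do not say that the 2 arrays of a group came from separate cultures, so all p-values measure the spread between these arrays, which may be technical.

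Per the file headers, the deposited scanner files were written by Agilent Feature Extraction 10.7.1.1 from 1 slide and 1 scan, and hold background-corrected processed signals as intensities, spot by spot, with flags. Each array has 45015 spots, of which 43376 are not controls, for 41000 different probes. The deposited value table of the series holds log2 values, not centred, with column medians of 8.3574 and 8.3531 (TBS 1 and 2) and 8.3574 and 8.3595 (GPBP-1 1 and 2). Its columns correlate with the log2 processed signals of their own arrays at r of 0.99896 to 0.99998, which settles their scale and direction, and their sorted values nearly coincide. The normalization recipe behind that table was not given in the sources used here, so it served only as an alternative.

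The log2 of the processed signal was taken, and the 75th percentile of each array's non-control spots was subtracted. Control spots and spots flagged as non-uniform or as population outliers were left out, and spots of 1 probe were averaged. A probe was kept where it was well above background on both arrays of at least 1 group. Each gene name of the array was represented by its kept probe of highest mean signal, which left 21013 genes. Levels are therefore log2 units relative to the 75th percentile of the array. Different probes are compared by brightness on the array only, not as amounts of transcript. Where a gene was not well above background on either array of a group, its fold is given as a lower bound. That bound sets the mean of the brighter group against, for each dimmer array, the higher of the probe's own signal and the lowest signal among probes well above background.

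Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Every adjusted p of a single gene comes from that fit. The moderated test had 4.65 degrees of freedom. Before the data were examined, 31 gene lists were fixed, holding 963 entries of which 860 were measured. They were tested with camera at a preset correlation between genes of 0.01, over lists with at least 5 measured members, with Benjamini-Hochberg adjustment over the lists. Camera asks whether a list moved relative to all other genes. Camera with an estimated correlation, camera at a preset of 0.05 and fry were run beside it, of which fry asks only whether the genes of a list move one way and sets them against no other genes.

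Genes are named in the text by a rule fixed at the same time. It takes up to 12 genes of each direction past the threshold with groups that do not overlap. Because no gene passed, the places were filled with the genes of smallest unadjusted p among those with a log2 fold change of at least 0.5 in size and groups that do not overlap. It also takes up to 4 members of each list by smallest unadjusted p, and the genes CERT1 and COL4A3. Some genes that the rule takes are not reported here. Current symbols came from a RefSeq gene table (assembly GRCh38.p14), through the RefSeq accession for 26386 probes, the array's own symbol for 2399 and a synonym for 596. The other 11619 probes kept the name on the array. Probe coordinates are those of the array files, whose genome build was not given in the sources used here.

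The fits were tested on simulated data for the comparison of 2 GPBP-1 with 2 TBS arrays, with 200 of 21013 genes changed and variances drawn from the fitted prior. Of genes changed by 2 log2 units 94.5% were called, of those changed by 1 unit 65.1%, and of those changed by 0.5 units 1.5%. An average of 4.8 unchanged genes was called per run over 5 runs. With an added shift of 0.3 log2 units in size to the 43 immediate early genes and no correlation between genes, camera called that list in 100% of 20 runs and made 1 call among lists sharing no gene with it. The lists called below had smaller medians, 0.02 to 0.22 in size. Their estimated correlations reached 0.77, for histone genes, so these runs do not give the power or false calls for them. No exact permutation of 2 against 2 arrays can give a two-sided p below 0.333. The number of arrays limits the precision.

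The alternatives fixed at the start were quantile normalization, the median in place of the 75th percentile, normexp background correction with an offset of 50, the authors' processed values, other filters on background, keeping outlier spots, testing every probe, averaging the probes of a gene, an intensity trend with a robust prior, the replicate number as a block, leaving out each array, and other thresholds. Others were chosen after seeing the data, namely normexp without spots whose local background exceeded 10 times the array's median, cyclic loess, and removal of a trend with probe GC content. A planned block for slide or scan was not run, since the 4 arrays share 1 slide and 1 scan. A test written for the closing section, whether cyclic loess removes the difference at low signal, was dropped because loess does so by construction.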

Results

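A549 cells, an epithelial line from a human lung adenocarcinoma, were profiled 3 h after the addition of 200 ng/mL recombinant extracellular GPBP-1 or of its buffer, TBS. GPBP-1 is a protein kinase that binds the Goodpasture antigen, the non-collagenous domain of the collagen IV chain encoded by COL4A3. There were 2 arrays in each group, each with 41000 probes. The 75th percentile of the signal was 3372 and 3147 on TBS arrays 1 and 2 and 3135 and 3223 on GPBP-1 arrays 1 and 2. Between 71.5% and 75.7% of non-control spots were well above background, and no such spot was saturated. Across genes, which are not independent replicates, the TBS arrays correlated at r = 0.997 and the GPBP-1 arrays at r = 0.997, while arrays of different groups correlated at 0.996 to 0.997. The 4 arrays lay on 1 slide, with TBS at positions 1 and 2 and GPBP-1 at positions 3 and 4, so position and treatment cannot be told apart.

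The comparison asks which transcripts differ in A549 cells 3 h after extracellular GPBP-1. The profiles of the groups lay close together. Of 21013 genes measured, 18854 (89.7%) had means within 1.2-fold of each other, and 159 differed by 1 log2 unit or more. With limma, 0 genes passed an adjusted p of 0.05, so 0 were called higher and 0 lower. An unadjusted p under 0.05 was reached by 1577 genes (7.5%), against 5.02% of the unchanged genes in the simulation. Of the 1577 genes, 1345 were higher and 232 lower with GPBP-1, a split that narrowed to 778 and 442 after quantile normalization. With no filter on background the share was 4.8%, at 1431 of 29823 genes. The median log2 fold change of all genes, 0.0353, was 0.0165 without TBS array 1 and 0.0526 without TBS array 2. The arrays of the groups did not overlap for 8579 genes (40.8%), where chance gives 33.3%. Without TBS array 1 the count of called genes was 28, and without TBS array 2 it was 24, with the lone control array assumed to vary like the GPBP-1 group. The sets shared 2 probes, and in 27 of the 28 and 23 of the 24 the TBS arrays lay more than 1 log2 unit apart.

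Among named genes the smallest p on the lower side belonged to TRARG1 (TUSC5 on the array), a regulator of glucose transporter trafficking in fat and muscle, probed at chromosome 17, 1203584 to 1203643. Its level was -5.02 ± 0.02 (SD, n = 2) with TBS and -6.58 ± 0.09 (SD, n = 2) with GPBP-1. The log2 fold change was -1.56 ± 0.08 (SE), with an adjusted p of 0.114. It passed the threshold after quantile normalization (adjusted p = 0.0438) and with the authors' processed values (adjusted p = 0.0498). These settings are alike, since the authors' sorted columns nearly coincide. It did not pass with no filter on background, where the smallest adjusted p of any gene was 0.763 (limma). Under normexp without bright-background spots that smallest value was 0.292. The smallest p of all came from THC2668335, an unnamed transcript at chromosome 18, 59415368 to 59415952, singled out after its values were seen. It measured -6.31 ± 0.16 with TBS and was not well above background on either GPBP-1 array, at least 2.02-fold lower, with an adjusted p of 0.0723. TRARG1 and THC2668335 were the 2 genes called after quantile normalization and with the authors' processed values.

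SOX3, a developmental transcription factor, was the brightest of the named genes on the higher side. Its probe at X, 139586024 to 139586083, read 1.45 and 0.98 with TBS and 2.77 and 3.20 with GPBP-1, a log2 fold change of 1.77 ± 0.22 (SE) with an adjusted p of 0.469. A second SOX3 probe gave 1.63. NTRK2, the receptor of brain-derived neurotrophic factor, had a log2 fold change of 0.92 ± 0.08 (adjusted p = 0.397), and CFAP44, a cilium component, one of 1.40 ± 0.15 (adjusted p = 0.465), although another CFAP44 probe gave 0.23. NTRK2 was dim, at -6.77 and -6.67 on TBS arrays 1 and 2, where the lowest signals well above background were -7.26 and -6.86. The other genes named on that side were also near the detection limit on the TBS arrays. CD93, a receptor of endothelial and myeloid cells, was not well above background on either TBS array and was at least 1.02-fold higher with GPBP-1 (adjusted p = 0.322). The corresponding bounds were 1.25-fold for GP1BA (adjusted p = 0.397), 1.41-fold for FLRT1 (adjusted p = 0.465), 1.13-fold for C16orf78 (adjusted p = 0.465) and 1.67-fold for CALML6 (adjusted p = 0.507). WDFY4 and SLC26A9 were also not well above background with TBS, and their GPBP-1 signals were too dim to give a bound above 1. GH1 and SLC30A2 were well above background on 1 of the 2 TBS arrays. Their log2 fold changes, which use both arrays, were 0.61 and 0.55.

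On the lower side, EDN2, which encodes the vasoconstrictor endothelin 2, was the brightest named gene, with a log2 fold change of -0.55 ± 0.22 (SE) and an adjusted p of 0.686. The values were -0.86 ± 0.14 for CCBE1, a secreted factor of lymphatic growth, and -0.66 ± 0.14 for NPBWR1, a neuropeptide receptor. ESYT3 was not well above background on either GPBP-1 array and at least 7.89-fold lower there (adjusted p = 0.575), but its TBS arrays differed by far more than the GPBP-1 arrays did, at -5.83 and -2.87. GSG1 likewise read -3.14 and -6.29 on the TBS arrays, against -6.82 and -7.08 with GPBP-1. RNF212, ASB2 and FAM86DP had log2 fold changes of -0.66, -0.50 and -0.53. CHADL, LGI2 and SPANXA2-OT1 were well above background on 1 of the 2 GPBP-1 arrays. Their log2 fold changes, which use both arrays, were -0.55, -0.74 and -0.66.

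**Figure D1:**
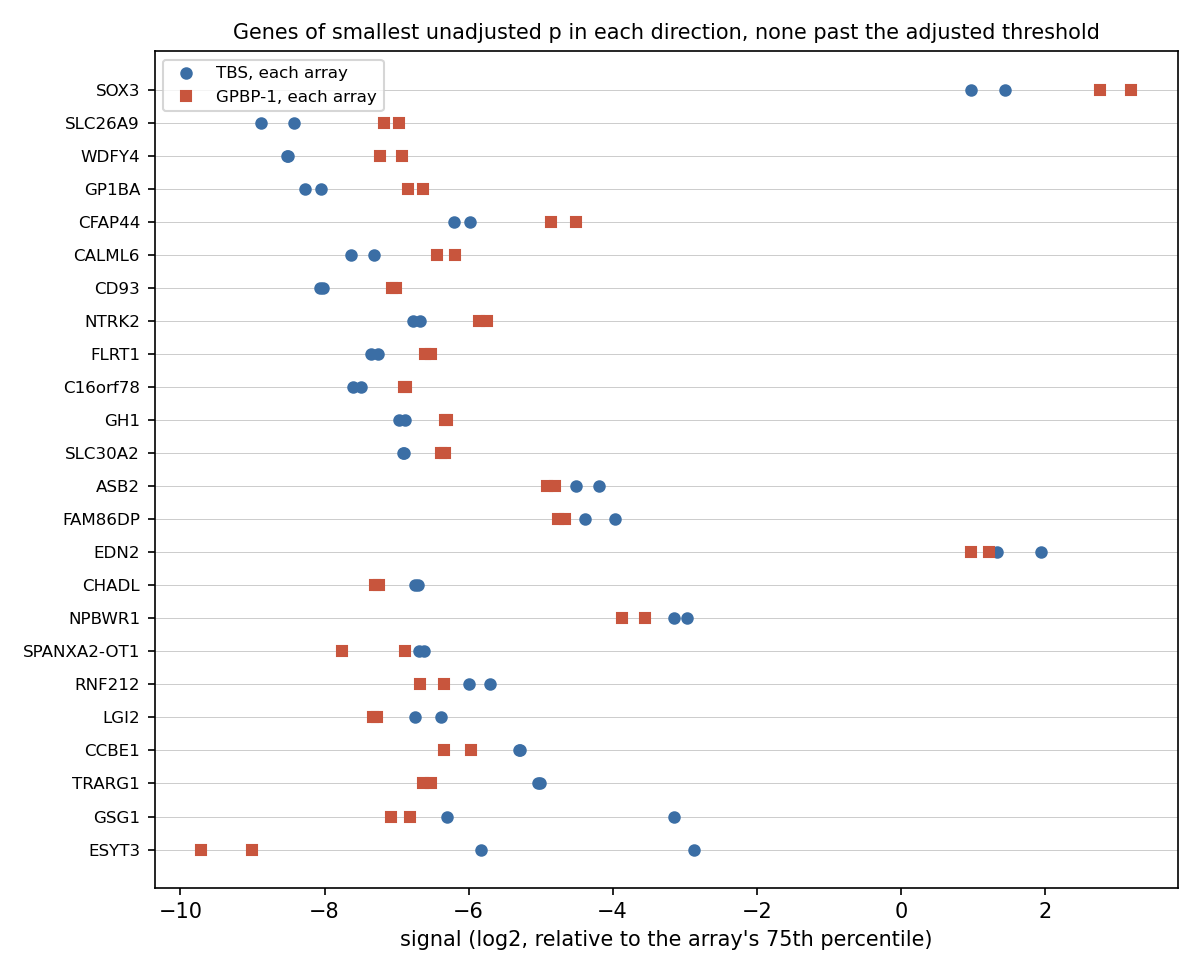
Signal of each named gene on each array, in log2 units relative to the array's 75th percentile, with TBS arrays as circles and GPBP-1 arrays as squares, ordered by log2 fold change. The groups do not overlap for any gene shown, none has an adjusted p under 0.05, and except for SOX3 and EDN2 the genes lie below -2.5.

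The gene encoding GPBP-1 itself, CERT1 (COL4A3BP on the array), differed by less than the spread between replicates. Its brighter probe, at chromosome 5, 74675151 to 74675210, read -0.16 ± 0.05 (SD, n = 2) with TBS and -0.18 ± 0.05 (SD, n = 2) with GPBP-1. The log2 fold change was -0.02 ± 0.07 (SE), with an adjusted p of 0.956, and the other probe, at 74667025 to 74667084, gave -0.08. COL4A3, whose product GPBP binds, was dim. Its log2 fold change was 0.19 ± 0.09 (SE) at the probe on chromosome 2, 228178994 to 228179053, with an adjusted p of 0.688. The other COL4A3 probe, at 228175622 to 228176518, was above background on 0 TBS arrays and 1 GPBP-1 array, and was not tested. Its mean of -7.29 with GPBP-1 lay below the lowest signals well above background on the TBS arrays (-7.26 and -6.86). No bound above 1 can therefore be given for it. The treatment was added protein, so the level of CERT1 does not check the labels.

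Of 31 gene lists, 9 passed the camera threshold relative to all other genes, 5 lower and 4 higher with GPBP-1, with median fold changes under 1.2-fold in every list tested. None of the 9 passed with an estimated correlation or with fry. On 4 arrays the test with an estimated correlation can hardly call a list, so its values do not tell lists apart. It gave an adjusted p of 0.574 for p53 targets, at 0.369 in the main setting, as for most of the 9 lists. G1/S and ceramide genes also went to 0.574, although their estimated correlations (-0.016 and -0.025) lay below the preset 0.01. The estimates of the other called lists lay above the preset. They were 0.031 for endothelial, 0.073 for immediate early, 0.15 for NF-kB and 0.31 for YAP genes. Ribosomal genes were at 0.31, leukocyte markers at 0.40 and histone genes at 0.77. For these lists camera at the preset may give p that are too small. No member of any of the 31 lists passed limma's threshold over all genes.

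NF-kB target genes, which encode inflammatory chemokines and survival factors, were lower, with a median log2 fold change of -0.07 and 22 of 30 members below 0 (camera, adjusted p = 5.1e-05). With an estimated correlation the adjusted p was 0.574, and with fry 0.428. An unadjusted p under 0.05 was reached by 5 members, and 0 passed over all genes and 0 when adjusted over the list alone. The chemokine genes CCL2 (-0.43 ± 0.15, SE), CCL20 (-0.38 ± 0.10) and CXCL2 (-0.24 ± 0.08) and the apoptosis inhibitor gene BIRC3 (-0.27 ± 0.09) had the smallest p. The list's median deviation from the gene means was 0.04 ± 0.06 (SD, n = 2) on the TBS arrays and -0.04 ± 0.004 on the GPBP-1 arrays. TBS array 1, at 0.08, stood farthest from the others. Without it the median was -0.05 (adjusted p = 0.0468), and without TBS array 2 it was -0.11. With no filter on background it was -0.05 (adjusted p = 0.0339), after removal of the probe GC trend -0.14, and under planned normexp -0.34, where the list did not pass (adjusted p = 0.805).

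Immediate early genes, which respond to growth factors and stress within the first hours, were lower in 29 of 43 members, with a median of -0.09 (camera, adjusted p = 2.4e-04; adjusted p = 0.574 with an estimated correlation). Their 4 members of smallest p included EREG (-0.32 ± 0.10, SE), SRF (-0.17 ± 0.08) and KLF6 (-0.15 ± 0.07, with other probes at -0.08 and 0.32), and also FOS on the other side at 0.21 ± 0.08. Targets of YAP and TEAD, the effectors of Hippo signalling, were lower in 18 of 22 members, with a median of -0.05 (camera, adjusted p = 0.0023; adjusted p = 0.574 with an estimated correlation). The YAP member of smallest p was RBMS3 (-0.16 ± 0.07), whose other probes gave 0.07 and 0.10, followed by ANKRD1 (-0.26 ± 0.13), CCN1 (-0.23 ± 0.14) and AMOTL2 (-0.13 ± 0.08). The medians of the YAP list on the arrays of the groups overlapped. When adjusted over the list alone, 0 members of either list passed. Without TBS array 1 neither list passed, with a median of -0.04 for immediate early genes (adjusted p = 0.0599) and -0.01 for YAP targets (adjusted p = 0.564). The YAP median was -0.02 without GPBP-1 array 1 (adjusted p = 0.168), and -0.12 without TBS array 2 and without GPBP-1 array 2. With every probe on its own it was -0.09.

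Ribosomal protein genes were higher in 53 of 55 members, with a median of 0.11 (camera, adjusted p = 7.1e-05; adjusted p = 0.574 with an estimated correlation). RPS10 (0.45 ± 0.07, SE), RPL7 (0.50 ± 0.09), RPS12 (0.39 ± 0.11) and RPL38 (0.26 ± 0.08) led the list, although further probes of RPL7 and RPS10 gave smaller values, 0.13 for RPL7. The direction of the list turned after quantile normalization (median -0.02, adjusted p = 0.429) and in the authors' processed values (median -0.01, adjusted p = 0.673). Without TBS array 1 the median was 0.06, and after removal of the probe GC trend 0.05. After cyclic loess it was 0.01, and the list did not pass (camera, adjusted p = 0.185). Replication-dependent histone genes, whose proteins build chromatin in S phase, were higher in all 17 measured members. Their median was 0.19 (camera, adjusted p = 7.4e-04, and 0.574 with an estimated correlation). That estimated correlation was 0.77, so the 17 members are not independent. The histone genes of smallest p were H2AC8 (0.25 ± 0.09), H2AC6 (0.33 ± 0.13), H2BC9 (0.16 ± 0.07) and H1-4 (0.34 ± 0.15). When adjusted over the list alone, 0 ribosomal and 0 histone genes passed. The histone median was 0.20 on GPBP-1 array 1 and -0.0004 on GPBP-1 array 2, against -0.17 and -0.02 on the TBS arrays. The list's median fold change was 0.11 without GPBP-1 array 1 (adjusted p = 0.312), 0.12 without TBS array 1 (adjusted p = 0.0976) and 0.31 without GPBP-1 array 2, and 0.11 after removal of the probe GC trend.

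**Figure D2:**
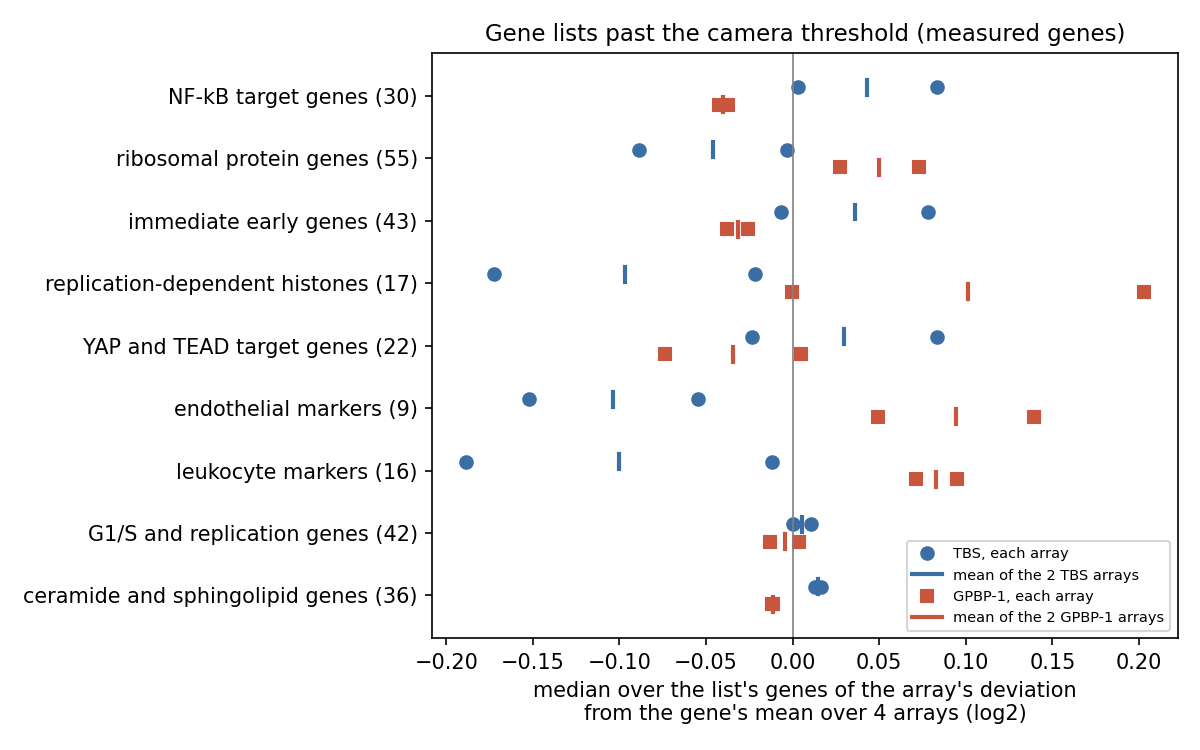
Median over each list's measured genes of the deviation of an array from the gene's mean over the 4 arrays, in log2 units, with TBS arrays as circles, GPBP-1 arrays as squares and group means as bars. NF-kB targets lie at 0.08 and 0.003 on the TBS arrays and near -0.04 on both GPBP-1 arrays, and the arrays overlap for YAP targets and for G1/S genes.

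The other lists past the threshold were close to it. Endothelial markers, a cell type not in the culture, were higher in 7 of 9 members (median 0.15, camera adjusted p = 0.0459; adjusted p = 0.574 with an estimated correlation), led by ENG, at least 1.23-fold higher, CDH5, at least 2.03-fold higher, and ROBO4, at least 1.07-fold higher. None of the 3 was well above background on a TBS array, so they passed the filter through the GPBP-1 arrays alone. With only genes above background on all arrays the endothelial adjusted p was 0.406, and with no filter on background the median was 0.03 (adjusted p = 0.977). CDH5 read -4.76 and -7.32 on the GPBP-1 arrays, so its bound rests on GPBP-1 array 1. One member, ENG, passed when adjusted over the list alone. Leukocyte markers were higher in 11 of 16 members (median 0.22, camera adjusted p = 0.0464, and 0.583 with an estimated correlation). Among them were CD3E at 0.30 ± 0.08, CSF1R at 0.43 ± 0.14 and HBB, a haemoglobin gene that the list includes, at 0.41 ± 0.15, all of them dim. Another CD3E probe gave -0.17. G1/S and replication genes were lower in 24 of 42 members (median -0.02) and ceramide and sphingolipid genes in 21 of 36 (median -0.02), each at a camera adjusted p of 0.0464 and at adjusted p = 0.574 with an estimated correlation. CERT1 encodes the ceramide transfer protein as well, and the ceramide members of smallest p went both ways, B4GALT5 (0.16 ± 0.09) and SMPD3 (0.24 ± 0.13) higher and UGCG (-0.19 ± 0.10) and SGMS1 (-0.18 ± 0.10) lower. RFC5 (-0.17 ± 0.08), RRM2 (-0.19 ± 0.09) and RFC4 (-0.20 ± 0.10) were among the G1/S members of smallest p, with LIG1 on the other side at 0.15 ± 0.07 and another RRM2 probe at 0.06. Genes in the signal decile of the G1/S list had a median of 0.005, and those in the decile of the ceramide list -0.003. After cyclic loess the camera adjusted p was 0.118 for G1/S and 0.128 for ceramide genes. For endothelial and leukocyte markers it was 0.0906. All 4 of these lists lost the threshold after quantile normalization, with adjusted p between 0.0678 and 0.112, and without TBS array 1, between 0.0599 and 0.363. With no filter on background the other 3 lost it too, at adjusted p = 0.208 for ceramide genes, 0.271 for G1/S genes and 0.11 for leukocyte markers. Endothelial markers also lost it without TBS array 2 (adjusted p = 0.104) and without GPBP-1 array 2 (0.0937), leukocyte markers without GPBP-1 array 1 (0.0998) or 2 (0.178), G1/S genes likewise (0.0569 without array 1), and ceramide genes without any 1 array. Without TBS array 1 the leukocyte median was 0.12, and the G1/S median ranged from -0.02 to -0.006 with 1 array left out.

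The other 22 lists did not pass, with adjusted p from 0.0555 to 0.876. The nearest were cholesterol synthesis genes (median -0.02), with IDI1 at -0.27 ± 0.08 (SE), and the amino acid response genes driven by ATF4 (median 0.08, 23 of 28 higher), with PSAT1 at 0.27 ± 0.09 and NUPR1 at 0.23 ± 0.07. The ATF4 list passed after quantile normalization (adjusted p = 0.0148) and cyclic loess (0.0116), but not with an estimated correlation in the main setting (0.574). Heat shock genes, at a median of 0.02 and an adjusted p of 0.236, also passed after quantile normalization, at a median of -0.05 (adjusted p = 0.0234). They did not pass after cyclic loess (median -0.02, adjusted p = 0.118), nor with an estimated correlation in the main setting (adjusted p = 0.574). Cholesterol genes passed with the median in place of the 75th percentile (median -0.06, adjusted p = 0.0467; 0.574 with an estimated correlation in the main setting). Basement membrane and collagen IV genes had a median of 0.003 (adjusted p = 0.36), with LAMA4 at 0.44 ± 0.09, and TGF-beta targets 0.003 (adjusted p = 0.198). Medians were 0.07 for interferon-stimulated genes (adjusted p = 0.394), 0.07 for STAT3 and acute phase genes (adjusted p = 0.369), 0.09 for Wnt targets (adjusted p = 0.208) and 0.08 for Notch targets (adjusted p = 0.236). In the Notch list 3 genes passed when adjusted over the list alone, MFNG at 0.35 ± 0.07, HEY2 at 0.41 ± 0.08 and DTX1 at 0.51 ± 0.12, but other probes of MFNG and HEY2 gave -0.26 and -0.02. HEY2 and DTX1 were also dim, at -6.77 and -6.62 with TBS, in the lowest decile of signal described below. Alveolar type II and lung epithelial genes had a median of 0.10 (adjusted p = 0.272), with SFTPD, a surfactant protein gene, at 0.74 ± 0.16. In none of the other 21 lists outside the called 9 did a gene pass over the list alone.

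Epithelial genes had a median of 0.09 (adjusted p = 0.236), mesenchymal genes 0.04 (adjusted p = 0.576) and markers of fibroblasts and smooth muscle 0.04 (adjusted p = 0.763). Matrix proteases and their inhibitors lay at 0.005 (adjusted p = 0.236), metallothioneins at 0.10 (adjusted p = 0.236), NRF2 targets at 0.05 (adjusted p = 0.285) and glucocorticoid response genes at 0.05 (adjusted p = 0.422). The unfolded protein response was at 0.01 (adjusted p = 0.348), hypoxia targets at 0.02 (adjusted p = 0.809), p53 targets at -0.002 (adjusted p = 0.369), oxidative phosphorylation at 0.05 (adjusted p = 0.439) and G2/M genes at 0.04 (adjusted p = 0.876). The median of all genes was 0.04, so that a list can lie above 0 and below other genes. In 10 lists, none of them past the threshold, the median, the mean or the direction of the test differed in sign.

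Dim genes as a class read higher on the GPBP-1 arrays. In the lowest decile of genes by signal the median log2 fold change was 0.17, with 73.7% of genes above 0 and 24.3% at an unadjusted p under 0.05. It declined to -0.003 in decile 7 and was 0.05 in the highest decile. The endothelial list, with a median signal of -5.91, lies in this lowest decile, the leukocyte list, at -3.92, in decile 3, where the median was 0.07, and ribosomal protein genes, with a median signal of 6.74, in the brightest. The filter on background may add to the difference at low signal, since a probe was kept through either group. On both GPBP-1 arrays and no TBS array 328 probes were well above background, against 13 the other way. Over all genes the median was 0.0353, against 0.0316 with genes above background on all arrays and 0.021 with no filter. The share of genes at an unadjusted p under 0.05 (limma) was 7.5%, 7.16% and 4.8% in these settings. The filter's effect by decile was not tested.

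**Figure D3:**
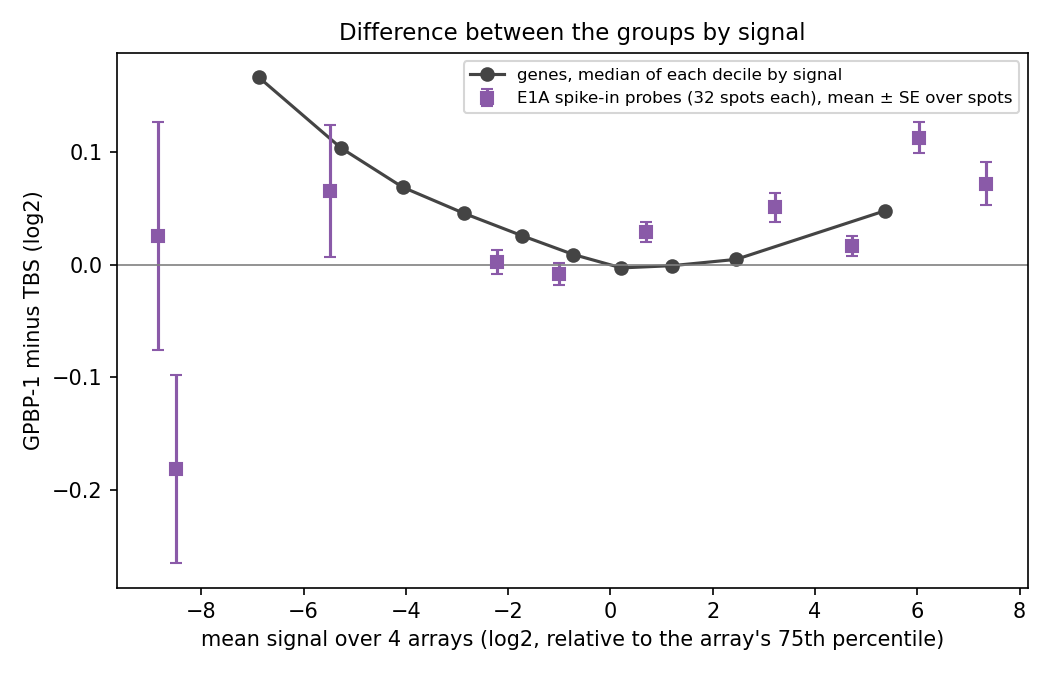
Difference between the groups (GPBP-1 minus TBS, log2) against mean signal over the 4 arrays (log2, relative to the 75th percentile), as medians of each decile of the genes and as means with SE over 32 spots for each E1A spike-in probe, whose RNA is added and not of the cells. Gene medians run from 0.17 at the lowest signal through about 0 to 0.05 at the highest, and the 3 brightest spike-ins lie, from the dimmest up, at 0.02, 0.11 and 0.07.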

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

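The alternatives with cyclic loess, GC trend removal and normexp without spots of bright local background were chosen after seeing the data. The count of 0 called genes (1577 at an unadjusted p under 0.05) held under 12 of 16 settings other than leaving out an array. Among the 12, the added demand for a log2 fold change of at least 1 could give no other count. The count became 2, both lower, after quantile normalization and with the authors' processed values, and 1 at an adjusted p under 0.1. Planned normexp gave 16860 calls, 5311 higher and 11549 lower, moved the median of all genes from 0.04 to -0.41, and shifted 16 lists. This traces to 2 spots on TBS array 1 and 5 on TBS array 2 with a local background over 10 times the array's median, since without such spots normexp gave 0 calls and 5 lists. Leaving out 1 array at a time gave 0 to 28 calls, 0 to 8 higher and 0 to 22 lower, and 2 to 7 lists.

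Against 9 lists shifted in the main setting, cyclic loess left 4 and added the ATF4 list, a preset correlation of 0.05 left 5, and an estimated correlation and fry left 0 each. With the replicate number as a replicate block there were 0 called genes and 8 lists. Deviations of same-numbered arrays correlated at -0.029 across genes, so no deviation shared by number was seen. The labels do not say whether same-numbered arrays share a culture or day. CERT1 changed sign without TBS array 2 (0.0146) and without GPBP-1 array 2 (0.020), both within its SE, and ranged from -0.0557 to 0.020 with 1 array left out. NF-kB targets did not pass under planned normexp (median -0.34, adjusted p = 0.805). There the test of 6 lists turned direction relative to other genes, at medians of -0.0726 (immediate early, whose median kept its sign), 0.0884 (YAP), 0.0730 (ceramide), 0.33 (G1/S), -2.17 (leukocyte) and -2.94 (endothelial). Under normexp without bright-background spots the ceramide and G1/S medians also changed sign, to 0.0026 and 0.0022, and neither list passed. With the median in place of the 75th percentile they were -0.061 and -0.063, and both lists passed. The ribosomal list turned after quantile normalization (-0.0151) and with the authors' values (-0.0117); the cause was not tested there. Of 143 named genes other than CERT1, planned normexp changed the sign of 76, averaging a gene's probes changed KLF6 and RBMS3, normexp without bright-background spots changed RPL38, and no other setting changed any that it measured (123 with genes above background on all arrays). Signal over background limits the dim genes most. In the lowest decile by signal the SD between TBS arrays was 0.37 log2 units, against 0.09 in the highest.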

Other observations

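Histone genes outside the fixed list also lay above 0. Among 82 families of genes sharing a symbol stem, formed after the data were seen, genes named HIST on the array had the smallest p, with 60 of 61 above 0 and a median log2 fold change of 0.23 (camera, adjusted p = 1.9e-10, and 0.604 with an estimated correlation). Of the 45 outside the fixed list 44 were above 0. The estimated correlation within the family was 0.765, so its genes are not independent. The family's median deviation was -0.19 and -0.04 on the TBS arrays and 0.23 and 0.01 on the GPBP-1 arrays, so that TBS array 2 and GPBP-1 array 2 lay closer to each other than to the other array of their group. Also past the threshold were RPL genes (median 0.10, adjusted p = 0.0074), ZNF genes (-0.01, adjusted p = 0.0132) and NUP genes (-0.05, adjusted p = 0.0214), none with an estimated correlation. Without TBS array 1 these 3 families did not pass (adjusted p = 0.278, 0.402 and 0.278), and after cyclic loess RPL (median 0.02, adjusted p = 0.437) and NUP (adjusted p = 0.245) did not.

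More probes were well above background on both GPBP-1 arrays and on no TBS array (328) than the other way round (13). Pairing TBS array 1 with GPBP-1 array 2 against the other arrays gave 229 and 13, so such one-sided counts also arise between arrays of mixed groups.

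Of the tests below, those of slide position, of TBS array 1, of the other splits and of the spike-ins at high signal were chosen after the results were seen. The pattern of dim genes reading higher on the GPBP-1 arrays (median 0.13 in the lowest 2 deciles) stays open as to its source. Array background could account for it, and the 1 E1A spike-in probe of like signal was higher by 0.0657 ± 0.059 (SE over 32 spots), over 0.5 of that difference but within 2 SE of 0 as well. The bound written beforehand asked only for 0.5 of the difference, and the requirement to exceed 0 by 2 SE was added after the value was seen, without which the value would count for array background. Below the signal of the genes, the negative control probe was at -0.16 ± 0.04 and the other 2 dim spike-ins at -0.18 ± 0.08 and 0.03 ± 0.10. All these SE measure the spread over spots and not the spread between arrays. The negative control read -9.34 and -9.02 on the TBS arrays and -9.17 and -9.51 on the GPBP-1 arrays, so the groups overlapped. The filter on background, which kept probes through either group, may add to the pattern and was not tested by decile. Position on the slide cannot be told apart from treatment, since 0 positions held arrays of both groups. A response of the cells to GPBP-1 was not tested apart from these.

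The higher ribosomal protein genes may reflect a difference of the arrays at high signal. The 3 E1A spike-in probes in the signal range of those genes, whose RNA does not come from the cells, were higher on the GPBP-1 arrays by a mean of 0.0674 ± 0.0084 (SE over spots), against 0.11 for the ribosomal median. They differed among themselves, at 0.02, 0.11 and 0.07 (SD 0.0484), so the size of this difference is uncertain. The SE over spots also leaves out the spread between arrays. The dimmest of the 3 read 4.75 and 4.69 with TBS and 4.69 and 4.77 with GPBP-1. Its groups overlapped, while those of the others did not. Cyclic loess brought the ribosomal median to 0.01 (adjusted p = 0.185). A part coming from the cells remains possible.

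For the 5 lists with the smallest p (NF-kB, immediate early and YAP lower, ribosomal and histone higher), a signal-dependent trend is argued against as the whole cause, since 4 of the 5 passed after cyclic loess, all but the ribosomal list. Probe GC content is likewise argued against, since 5 of 5 passed after its trend was removed. A single array standing apart remains open. Without TBS array 1 the differences of the lists from all genes kept 0.617 of their size (median of the 5), and 2 lists passed, NF-kB targets and ribosomal genes. Without GPBP-1 array 1, 3 lists passed, and the ribosomal and histone differences kept 0.605 and 0.488 of their size. Of the 3 splits of the 4 arrays into pairs, 1 shifted as many as 9 lists, the real one, and the highest of the others shifted 6, among them the same 5, but 3 splits are too few for a share under 0.05. A response to GPBP-1 therefore remains an untested possibility beside a difference between single arrays.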
